A study of Caenorhabditis elegans with 4 samples.

How the data were processed

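COH-1 is a kleisin, the subunit that closes the ring of cohesin, the complex that holds sister chromatids together and folds chromosomes. Its binding along the genome was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in *Caenorhabditis elegans* young adults that contain a germline. The worms carried fem-2(b245), an allele of a gene needed for male development and for making sperm, and were grown at 20 °C per the series record. Per the labels' protocols, frozen and ground worms were crosslinked for 20 minutes with EGS and for a further 10 minutes with EGS plus formaldehyde, then sonicated. EGS is a crosslinker that joins proteins. The labels call the worms young adults, while their growth protocol describes the harvest of gravid adults. The immunoprecipitation used a rabbit polyclonal antibody raised against COH-1, whose catalogue number differs between the series title and the antibody description. The labels give 4 samples, 2 immunoprecipitated (ChIP replicates 1 and 2) and 2 input DNA samples numbered the same way. No processed file of the input samples was used here, so the inputs enter only through whatever use the authors' peak calling made of them, which is not given in the sources used here.

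The deposited values are 3 peak lists, 1 for each ChIP replicate and 1 for the series as a whole, called the series list below. Reads were aligned with BWA to ce10, per the submitters' processing notes, and the file headers give WormBase WS220 as the genome build. The source column of the files names MACS in the replicate lists and MACS v2 in the series list. Caller versions, thresholds and filters, and whether the series list was called on pooled replicates, are not given in the sources used here. Each deposited peak carries a score from the authors' peak caller, and no source says what that score measures. In the replicate lists no score was below 50, and 7 peaks of replicate 1 and 373 of replicate 2 shared the value 3100, so the strongest peaks of replicate 2 are poorly ordered. In the series list scores ran from 1.3 to 143. The scores were therefore used only to rank or filter peaks within their own list. The lists give no read counts, so the sequencing depth is unknown, and exact (Clopper-Pearson) 95% binomial intervals given for shares of peaks cover counting error only and treat peaks as independent, which neighbouring peaks are not. Nothing in the labels says that the replicates came from separate worm cultures, so differences between the lists may be technical. The p-values come from peaks and chromosomes within these lists and do not cover variation between cultures. The name under which the replicate 2 list was deposited also carries a further gene name that no label explains.

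Everything else was computed from the positions, widths and scores in the lists with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. Lists were compared by overlap of at least 1 bp. The share of a list found in another was tested against 1000 circular shifts of its peaks along each of the 6 nuclear chromosomes, which keep peak widths, spacing and numbers per chromosome (one-sided permutation test; the smallest p it can give is 0.001). Scores of peaks found and not found in the other replicate were compared by the difference of medians with 100000 permutations (two-sided; smallest p 1e-05), and the same differences were set against those of circularly shifted peaks. The length of each chromosome was taken as the largest peak end in any list, 100.2 Mb over the 6 nuclear chromosomes. Peak density on X was compared with that on the autosomes by the rank of X among the 6 chromosomes, an exact permutation test that cannot go below p = 0.167. Each chromosome was divided into 3 equal parts, and peaks per Mb in the middle part were compared with the mean of the outer parts by an exact two-sided sign-flip permutation test over the 6 chromosomes, whose smallest p is 0.0312. Clustering was measured as the share of neighbouring peaks separated by at most 5 kb, against 1000 uniform random placements of the same peaks. Simulated lists kept the real widths but placed peaks uniformly at random, so they do not show how the tests behave on unevenly placed peaks. On unrelated lists of this kind the shift test gave a share -0.588 percentage points from the mean of the shifts, where the true value was 0 (permutation p = 0.756, replicate 1 list in replicate 2 list, 2587 peaks). On a list thinned in the outer parts, the test of chromosome parts returned a mean log2 ratio of 1.03 where the true value was 1 (series list, 10491 peaks).

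The tests of the main comparisons, the choice of named peaks and most alternatives were fixed before the data were examined. The shift test of the score and width differences, the correlation across windows and the descriptions of single windows, of wide peaks and of stretches without peaks were added after. Named peaks are the 10 with the highest score in the series list that both replicate lists overlap, and the 3 highest of each replicate list that the other does not overlap, ties being ordered by position. The planned comparisons with gene starts and with 28 gene lists were not run, because the gene table at hand is of assembly WBcel235 and not of the build the files use, so peaks are given by WS220 coordinates without gene names. Coordinates count from 1. Alternatives were other overlap rules, the upper 50% of each list by score, lists of equal length, merged peaks, other chromosome parts and distances, and each replicate list in place of the series list. The 4 mitochondrial peaks of the series list were left out of every test along chromosomes.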

Results

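COH-1 occupancy was described by 3 peak lists. The replicate 1 list held 2587 peaks covering 8.30 Mb and the replicate 2 list 3714 peaks covering 11.7 Mb, or 3151 ± 797 peaks (mean ± SD, n = 2). The series list held 15765 narrower peaks covering 10.1 Mb. Median peak width was 1897 bp in replicate 1, 1573 bp in replicate 2 and 322 bp in the series list. Between 8.28% and 11.7% of the nuclear genome lay inside peaks, depending on the list. The files name the caller as MACS v2 for the series list and as MACS for the replicate lists, and no thresholds were given, so peak numbers were not compared between them as amounts of binding. Read depth was not given, and input DNA, the background of the assay, had no values of its own to set beside these.

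The first comparison was between the replicates, which tells how far the map of COH-1 repeats. Most of the replicate 1 map was recovered in replicate 2, whereas about 1 peak in 2 of the longer replicate 2 list had a partner. Of the 2587 replicate 1 peaks, 2253 were overlapped by a replicate 2 peak (87.1%, 95% interval 85.7 to 88.4). Of the 3714 replicate 2 peaks, 1903 were overlapped by a replicate 1 peak (51.2%, 95% interval 49.6 to 52.9). The shared sequence was 6.95 Mb, which is 83.7% of the bases in replicate 1 peaks and 59.5% of those in replicate 2 peaks. Circularly shifted peaks gave a mean of 18.6% and a highest value of 28.2% for replicate 1 in replicate 2, and 13.3% and 19.6% for the opposite direction, so both observed shares exceeded all 1000 shifts (permutation p = 0.001, the smallest possible). Across 998 windows of 100 kb, the percentage of bases inside peaks correlated between replicates with Spearman's rho = 0.90 and Pearson's r = 0.85. These are correlations across windows of the genome, and windows are not independent replicates. When both peaks of a pair had to share at least 50% of their length, the recovered shares were 51.9% of replicate 1 and 36.2% of replicate 2.

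**Figure D1:**
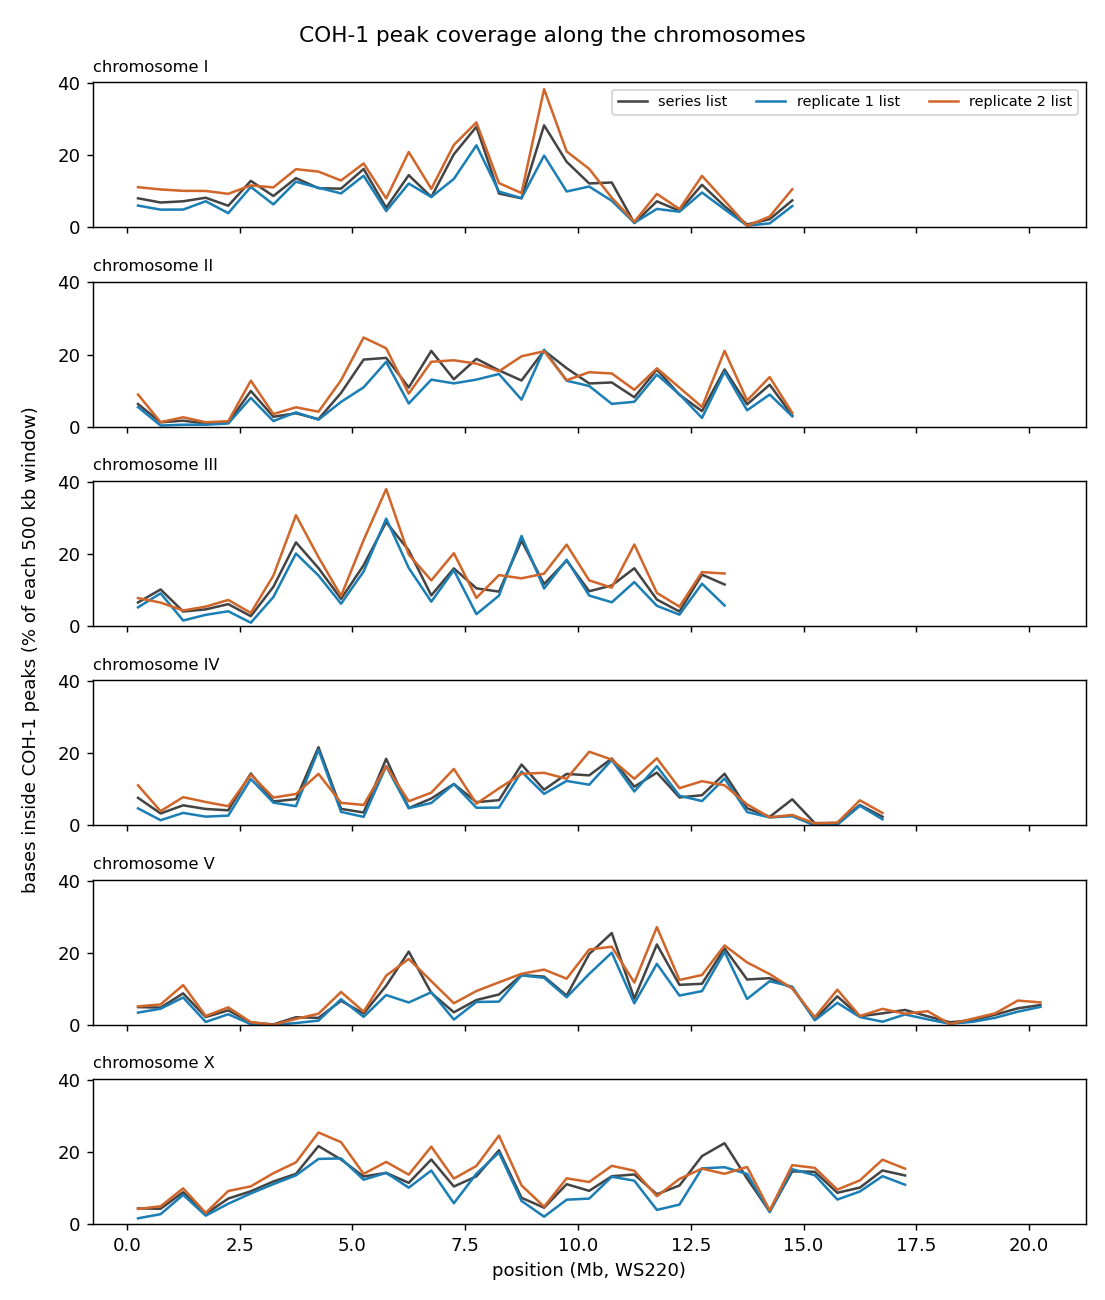
Percentage of bases inside COH-1 peaks (y axis) in consecutive 500 kb windows along each nuclear chromosome (x axis, Mb in WS220), for the series list and both replicate lists; the incomplete last window of each chromosome is not drawn. The 3 lines rise and fall together along most of each chromosome. Among other stretches, coverage is low over much of the left part of II, the right end of IV and both ends of V.

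Recovery rose with peak score in replicate 2, and less clearly in replicate 1. Found peaks were also wider in both lists, and score and width were not told apart. Among the 25% of replicate 2 peaks with the lowest scores, 18.2% were found in replicate 1, rising to 31.1%, 60.5% and 95.2% in the next 3 parts. Found replicate 2 peaks had a median score of 1075 against 145 for those not found, and a median width of 3070 bp against 1134 bp (permutation test, two-sided p = 1e-05 for both, the smallest possible). Wide peaks overlap others more often by chance, and circularly shifted peaks gave mean differences of 195 in score and 548 bp in width; the observed 929 and 1936 bp exceeded all 1000 shifts (one-sided permutation p = 0.001 for both). In replicate 1 the recovered share was 78.5% in the lowest part, 86.2% and 92.9% in the middle parts and 90.7% in the highest. Found replicate 1 peaks had a median score of 164 against 90.4 for those not found (permutation test, two-sided p = 1e-05), but shifts gave a mean difference of 46.0 and up to 106, so the observed 73.9 missed the 0.05 threshold against them (one-sided permutation p = 0.0659).

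**Figure D2:**
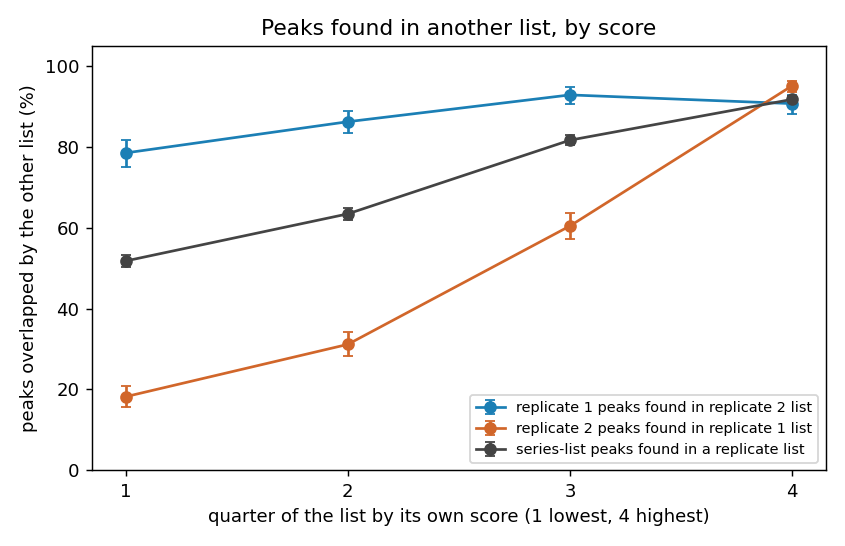
Share of peaks overlapped by another list (y axis, %) in 4 equal parts of each list ordered by its own score (x axis, 1 lowest), with exact 95% binomial intervals as bars. Replicate 2 peaks go from 18.2% to 95.2%, whereas replicate 1 peaks stay between 78.5% and 92.9%.

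The 10 highest-scoring series peaks overlapped by both replicate lists lay on 5 of the 6 nuclear chromosomes. In the series list, 8 of the 10 were wider than 5 kb. Their order rests on the series score alone, and not all were among the strongest peaks of replicate 1. Over the V site at 9546361 the replicate 1 peak scored 179, near that list's median of 150. The series peak with the highest score spanned 12609976 to 12620299 on chromosome III. Replicate 1 called a peak of 17328 bp over it and replicate 2 a peak of 25245 bp, both at the score of 3100. Next came a peak of 19141 bp at 7074378 to 7093518 on I (score 101), a peak of 13506 bp at 15602009 to 15615514 on X (99.1) and a peak of 10369 bp at 8789507 to 8799875 on IV (98.4). A second X site, 16926834 to 16933735, scored 88.5. On V, near its left end, 2 sites at 1145733 to 1152046 and 731135 to 736622 scored 87.3 and 85.1. A site near the left end of III, 353768 to 360792, scored 85.8. The 2 narrowest of these 10 sites were 1128 bp at 2774395 to 2775522 on IV (score 85.6), inside a replicate 2 peak of 22512 bp, and 828 bp at 9546361 to 9547188 on V (79.4). None of the 10 was on chromosome II.

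Some strong peaks of one replicate had no partner in the other. In replicate 1 these were led by 5584002 to 5591997 on IV (score 2753 in that list), 10744803 to 10749319 on I (2331) and 8791084 to 8796545 on III (1926), and the nearest replicate 2 peaks lay 20979, 25100 and 15410 bp away. In replicate 2 they were 3109565 to 3117563 and 13050543 to 13075895 on III, both at 3100, and 13647302 to 13666779 on V at 3096. Their nearest replicate 1 peaks lay 2206, 3827 and 69800 bp away. All 6 regions overlapped peaks of the series list. The widest replicate 2 peak, 48409 bp, lay on V in the window 6200001 to 6300000, a window singled out after its values were seen. Peaks covered 60.4% of that window in replicate 2, 57.3% in the series list and 7.12% in replicate 1.

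The series list overlapped nearly every replicate peak by at least 1 bp and held many further peaks. It overlapped 2581 of 2587 replicate 1 peaks (99.8%) and 3594 of 3714 replicate 2 peaks (96.8%). In bases, it covered 79.1% of the sequence in replicate 1 peaks and 66.8% of that in replicate 2 peaks. A replicate 1 peak that it overlapped held a mean of 2.64 series peaks, and a replicate 2 peak 2.90. Of the 15765 series peaks, 5700 (36.2%, 95% interval 35.4 to 36.9) were overlapped by both replicate lists, 1017 (6.45%) by replicate 1 alone, 4660 (29.6%) by replicate 2 alone and 4388 (27.8%) by neither. The share in both exceeded all 1000 circular shifts (permutation p = 0.001). The series list may rest on the same ChIP reads as the replicate lists, so overlap between them is no independent support for the peaks. Median score was 8.85 for series peaks in both replicates and 4 for those in neither, and median width was 602 bp against 214 bp. Of 49 series peaks of 10 kb or more, 27 were in both replicate lists, 16 in 1 and 6 in neither. The widest in both replicates were at 11460322 to 11486742 and 6238209 to 6262394 on X and at 10707380 to 10731521 on V.

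Peaks were then compared between the X chromosome, which is under dosage compensation in hermaphrodites, and the autosomes. Chromosomes III and X carried the densest COH-1 peaks and V the sparsest, in every list. In the series list there were 191 peaks per Mb on III, 186 on X, 162 on I, 158 on II, 140 on IV and 122 on V. X had 1.23 times the peak density of the pooled autosomes in the series list, 1.41 times in replicate 1 and 1.19 times in replicate 2. For peaks present in all 3 lists the ratio was 1.33. In bases covered, X was at 1.25 ± 0.08 times the autosomes (mean ± SD of the replicate lists, n = 2). X ranked second of the 6 chromosomes in the series and replicate 2 lists and first in replicate 1 (exact rank p = 0.333 and 0.167, one-sided), so X did not stand apart from the autosomes by this test, which could not have gone below 0.167.

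The last comparison along the chromosomes was between their centres and arms, which in this species differ in gene content and recombination. Repeats and mappable sequence of the parts were not examined and the inputs had no values, so a technical share in any difference cannot be judged. In every list, COH-1 peaks were denser in the middle part of each of the 5 autosomes than in the mean of its outer parts, while on X the middle and the mean of the outer parts were at similar density. X was not evenly covered at a finer scale, which was looked at after the data had been seen: of 9 equal parts, the first held 101 series peaks per Mb and the third 257, and the third part was denser than the first in both replicate lists, at 54.6 against 24.5 per Mb in replicate 2. On III in replicate 2 the right part, at 48.3 peaks per Mb, was denser than the middle at 45.9. In the series list the middle part of V held 202 peaks per Mb against 89.5 on the left and 73.3 on the right. II held 237 in the middle, 81.1 on the left and 155 on the right. The middle-to-outer ratio was 2.48 on V, 2.01 on II, 1.73 on I, 1.69 on IV, 1.31 on III and 1.06 on X. The mean log2 ratio was 0.73 ± 0.44 (SD over 6 chromosomes), above 0 on 6 of 6 chromosomes (exact sign-flip permutation test, two-sided p = 0.0312, the smallest possible). It was 0.70 in replicate 1, where 5 of 6 chromosomes had the denser middle (exact p = 0.0625), and 0.55 in replicate 2 with 6 of 6 (exact p = 0.0312). The test also missed the 0.05 threshold with the upper 50% of series peaks by score (0.61) and with only peaks in all 3 lists (0.88), both at exact p = 0.0625. The log2 ratio on X was 0.08 in the series list, -0.08 in replicate 1 and 0.12 in replicate 2, the lowest of the 6 chromosomes each time (exact rank p = 0.167, the smallest possible), while the 5 autosomes averaged 0.85 ± 0.34 (SD) in the series list.

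**Figure D3:**
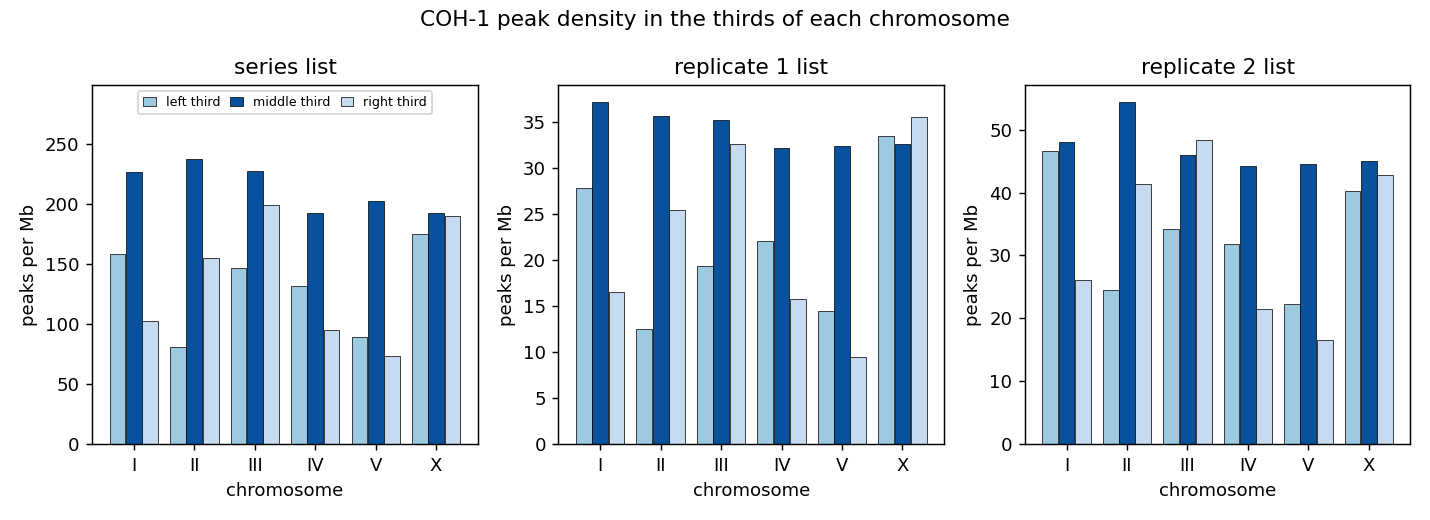
COH-1 peaks per Mb (y axis, starting at 0, scaled per list) in the left, middle and right part of each nuclear chromosome (x axis), for the series list and each replicate list. The middle bar is the highest on I, II, IV and V in each list, though on I in replicate 2 only by 48.0 against 46.6 on the left. On III it is the highest in the series and replicate 1 lists but not in replicate 2, and on X the 3 bars are nearly level.

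Peaks lay closer together than under uniform random placement, which ignores the denser chromosome middles and so makes some excess certain. In the series list 86.1% of neighbouring peaks lay within 5 kb of each other, against 59.0% under uniform random placement. Some of these neighbours may be parts of 1 region, since 70.7% of replicate 1 peaks and 60.8% of replicate 2 peaks overlapped 2 or more series peaks. The shares were 55.2% against 13.6% in replicate 1 and 60.5% against 19.4% in replicate 2, each above all 1000 placements (permutation p = 0.001). Conversely, long stretches held no peak in any list, the longest being 462 kb on the left arm of V (2733495 to 3195135) and 341 kb on its right arm (19058438 to 19399178). Of 998 windows of 100 kb, 83 had no peak in any list. The window with the highest share of bases inside series peaks was 7500001 to 7600000 on I, at 62.4% in the series list, 37.7% in replicate 1 and 55.4% in replicate 2.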

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

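All tests in this part were chosen after the overlaps between the lists had been seen. The tests by peak width, except that of peaks of 10 kb or more, were chosen before the shares by width were known, but after single wide unmatched regions had been noticed. The design has no biological contrast, so no biological explanation was tested for the patterns between the lists.

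The series list holds 4 peaks on the mitochondrial genome, a signal outside the nuclear chromosomes that the comparisons along chromosomes left out, although the peaks count among the 15765 of the overlap shares. They cover 94.4% of the 12910 bp up to the end of the last of them, with scores from 19.2 to 23.1, and neither replicate list has a mitochondrial peak.

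The first pattern is the 4388 series peaks that neither replicate list overlaps. Wide series peaks left out of the replicate lists are argued against as the cause of the pattern as a whole. Only 18 of its peaks (0.410%) were 5 kb or wider and 97.3% were under 1 kb. In the top 25% of scores the unmatched share was 9.50% under 1 kb, 6.26% from 1 to 5 kb and 8.41% at 5 kb or more. These shares do not decide whether width matters, since wide peaks overlap others more often by chance. Not found in replicate 1 were 32.0%, 9.76% and 19.2% of the same classes, and in replicate 2 16.0%, 15.7% and 19.6%. For the peaks of 10 kb or more the explanation stays open, with 12.2% (6 of 49, 95% interval 4.63 to 24.8) in neither list. Wide regions called as several narrow series peaks were not tested. Signal too weak for the replicate lists also stays open, since the unmatched share of 48.2% in the lowest 25% of series scores and 8.22% in the highest are the values that raised it. Multicopy sequence handled differently between the lists stays open, since the mitochondrial genome and the last 20 kb of chromosome I, the only places examined, hold only 7 series peaks, all 7 unmatched, which are 0.160% of the pattern.

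The second pattern is the peaks found in only 1 replicate. The unexplained gene name attached to the replicate 2 list raised the possibility that it was made from a target that occupies other regions. This is argued against for the strongest 25% of that list only, of which replicate 1 also found 95.2%, a value seen before the test was chosen. A target that shares those strong regions was not tested, so the overlap does not settle what the list was made from. Lower sensitivity of the replicate 1 list stays open for the unmatched replicate 2 peaks, since the 18.2% of the weakest 25% that were found is the value that raised it. Lower sensitivity of the replicate 2 list stays open in the same way for the 334 unmatched replicate 1 peaks, with 9.27% unmatched in the strongest 25% of that list and 21.5% in the weakest. Wide regions left out of the replicate 2 list cannot be told apart from chance, with 11.1% unmatched in the wider 50% of strong replicate 1 peaks and 7.41% in the narrower (Fisher's exact test, two-sided p = 0.106).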

How the results depend on the processing

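None of 42 alternatives to the main comparisons reversed its direction, and 5 lost the 0.05 threshold. The other 37 are weak evidence of stability: the 6 for X could not pass it, and those for overlap, clustering and replicate 2 peak strength stayed at or near the smallest p even where the values moved. Against circular shifts, chosen after seeing the data because wide peaks overlap more by chance, the replicate 1 differences between found and not found peaks were 27.9 in score and 62.4 bp in width beyond the shift mean (one-sided permutation p = 0.0659 and 0.33). The other 3 losses concern the denser chromosome middle (mean log2 ratio 0.73, exact p = 0.0312). With the upper 50% of series peaks by score it was 0.61, and with only peaks in all 3 lists 0.88, both at exact p = 0.0625; with either replicate list alone it ran from 0.55 to 0.70, the latter, without replicate 2, at exact p = 0.0625. In replicate 1 and in the peaks of all 3 lists X had the sparser middle (log2 ratios -0.08 and -0.01), and 1 such chromosome is enough to miss the threshold. For the upper 50% by score the same p-value means that 1 chromosome again lacked the denser middle, but which one was not recorded. The share of series peaks in both replicates, 36.2%, fell to 2.40% under reciprocal overlap of 50%, which narrow peaks inside wide ones cannot meet. That rule kept 5 of the 10 named peaks in both replicate lists, 4 in 1 and 1 in neither. With the replicate 2 list cut to its strongest peaks, in a number equal to the replicate 1 list, 80.3% of replicate 1 peaks were recovered. Of the replicate 2 peaks that remained after the cut, 65.4% were recovered, so this share does not cover the weaker peaks. The X-to-autosome ratio stayed between 1.17 and 1.41; its lower end, from the strongest replicate 2 peaks in a number equal to the replicate 1 list, was chosen after seeing the data. Unknown read depth limits all of this: absence of a peak from a list does not show absence of binding. No paired analysis was possible because the input samples that share replicate numbers with the ChIP samples have no values here. The planned comparisons with gene starts and gene lists, and their alternatives, were not run.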

Other observations

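The densities in this part were looked at after the data had been seen. A comparison of the outer parts by the side of the meiotic pairing centre, also chosen after, was run in an earlier draft and then dropped. The sides were given from memory with no source at hand. Its outcome depended on the side taken for V, so no test is given.

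The outer parts of most chromosomes were not alike. In the series list the left part of II held 81.1 peaks per Mb and its right part 155. The left part of III held 147 against 199, the right part of I 102 against 159 on its left, and the right part of IV 94.8 against 132. On X the left part held 175 and the right 190. V held 89.5 on the left and 73.3 on the right. Gene content, repeats and mappable sequence of these parts were not examined, since no genome of the build was used here.

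The right end of chromosome I carried a series peak of 11163 bp at 15060211 to 15071373 with a score of 44.2. It lay in the last 20 kb of the chromosome, examined above for multicopy sequence, an explanation that stayed open. The last replicate peaks on that chromosome ended at 14955167 and 14972248.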
